A study of Drosophila melanogaster with 3 samples.

How the data were processed

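Anti-GFP chromatin immunoprecipitation and sequencing was done on whole embryos (10 to 24 hours) of a fly line with a C-terminal GFP fusion of PHDP, in 3 biological replicates. Chromatin was fragmented by sonication, with a size range of 200 to 800 (unit not stated), per the labels. Per the file headers and accompanying notes, each replicate's peaks were derived by the authors from that replicate's alignment and 1 shared control, the pooled peaks from the 3 alignments and that control, and the IDR list from the 3 replicate lists and the pooled list, all on dm6. The aligner and peak caller are not given in the sources used here. The control itself and the signal tracks were not analysed here.

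Each peak has a signal value set by the authors, which is described here as deposited, and a −log10 q value, also deposited by the authors. The signal was used only to describe and rank peaks within a list: pooled signals were close to the sum of the replicate signals (median ratio 0.999), so the scale differs between lists. The −log10 q values reach a ceiling (4.24 in all 7092 IDR peaks) and were not used for ranking. Their lowest value in the pooled list is 0.348, so the weaker pooled peaks include peaks of weak support. Each replicate and pooled list holds exactly 30000 peaks, so numbers of peaks are not compared. The sequencing depth is unknown from these files, and intervals given cover counting error over peaks only. No peak was identical between replicates. Arms 2L, 2R, 3L, 3R, 4 and X were analysed, and mitochondrial peaks were left out.

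Coordinates are 1-based on dm6. Genome sequence of the same assembly (release 6) and the Ensembl release 115 annotation (BDGP6.54) were used. A summit was promoter-proximal within 500 bp of any annotated start site, and otherwise in an exon, an intron or intergenic sequence. Random backgrounds kept the number of peaks per arm (1000 placements for region shares, 100 for replicate overlap). Motif windows covered 100 bp either side of the summit, against a window centred 500 bp away. A gene was bound when an IDR summit lay within 1 kb of a start site, so that 1 peak can count for several genes, and Fisher's exact tests were two-sided with Benjamini-Hochberg adjustment over 16 lists. Random lists were drawn 10000 times within deciles of gene length. The surroundings of PHDP and w were windows of 50 kb. Errors are SDs over the 3 replicates, or their 3 pairs for overlap and correlation. They use the strongest 5000 peaks of each replicate for overlap, region and arm shares, words, gene lists and summits per gene. Signals use the matched peak in each replicate list, and the promoter signal difference and the correlation use IDR peaks matched in the replicates. Rank bins, peaks ranked below 7092 and the percentiles of PHDP and w use the full replicate lists.

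The groups, tests, gene lists, words, main settings and most alternatives were fixed before the data were examined. Named peaks and genes followed a rule fixed then: the 10 strongest IDR peaks, the 10 genes with most IDR summits, 3 bound and up to 2 unbound members of each list that passed, and PHDP and w. Alternatives were other overlap rules and list depths, stricter peak sets, other promoter limits, other motif windows, shuffled windows, other rules linking peaks to genes, other locus windows and leaving out each replicate. For most results this last kept the IDR peaks matched within 100 bp in the 7092 strongest peaks of both other replicates. Separate motif tests in promoter-proximal and other peaks, arm shares without each replicate, and the paired-like list without PHDP were chosen after seeing the data.

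The calculations were tested on simulated data. Randomly placed peaks gave a promoter share with p under 0.05 in 4 of 100 sets, and 0 of 18 words were called in randomly placed peaks. The first check drew peaks as the random background does, so it tests only the calculation. The second does not cover the lower GC of real summits (34.6% against 43.0% in flanks). A P3 word planted under 10% of peaks gave an excess of 9.76 percentage points and was called, with 2 words lacking TAAT also called in that set. Genes bound at random gave 0.02 called lists per set over 13945 genes, and a muscle list bound at 70% was called in 88 of 100 sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.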

Results

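GFP-tagged PHDP was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 10 to 24 hours. PHDP is a homeodomain protein of the paired-like class, a family of transcription factors that bind AT-rich DNA. The embryos came from a transgenic line in which PHDP carried green fluorescent protein at its C terminus, and an antibody against that tag was used. The series held 3 biological replicates of 1 group, and no contrasting group, such as embryos without the tag, was analysed here. Peaks that the antibody would give without PHDP can therefore not be separated from PHDP binding, and a gene called bound here is one with a peak nearby. Each replicate's peak list, and a list called on the pooled replicates, held exactly 30000 peaks. A list filtered by irreproducible discovery rate (IDR) held 7092 peaks, which were the 7092 strongest of the pooled list. Median peak widths were 400, 356 and 380 bp in replicates 1, 2 and 3. Sequencing depth is unknown from these files, so no interval that needs read counts is given, and the fixed list length means that peak number says nothing about how much was bound.

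The replicates placed their strongest peaks at largely the same positions. Of the 5000 strongest peaks of a replicate, 76.6% ± 0.920 (SD, n = 3 pairs) had a summit within 100 bp of one in another replicate. The lowest pair, replicates 1 and 2, shared 75.7%, and the highest, replicates 2 and 3, shared 77.5%. Randomly placed peaks gave 0.750% on average and at most 0.987% in 100 placements (permutation p = 0.0099, the smallest that 100 placements can give). In all, 6421 of the 7092 IDR peaks (90.5%) had a matched summit in all 3 replicates, but that list was derived from the replicate lists, so its filter favours such matches. Across IDR peaks matched in both members of a pair, the authors' signal correlated between replicates with a mean Spearman correlation of 0.801 ± 0.0191 (SD, n = 3 pairs). That correlation is across peaks, which are not independent replicates.

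The strongest peaks lay mostly close to the start of a gene. The highest signal of the IDR list, 6985, was in an intron of CG11050 (FBgn0031836), in a peak at 2L:6612331-6612991 of dm6, with its summit 1018 bp downstream of the nearest start site. Its signal in the replicate lists averaged 2319 ± 439 (SD, n = 3), and it ranked 2, 1 and 1 in replicates 1, 2 and 3. The next peak, 3L:19590403-19590832, had its summit at -86 bp from the start site of CG14100 (FBgn0036889) in intergenic sequence, with a signal of 2295 ± 442 (SD, n = 3). The peak at 2L:480520-481345 was nearest to cbt (FBgn0043364), a zinc finger transcription factor gene, but lay in an intron of ush, with a signal of 2053 ± 291 (SD, n = 3). Peaks followed upstream of Ugalt, a nucleotide sugar transporter gene, with the summit at -28 bp in X:2703656-2704096 and a signal of 2042 ± 374 (SD, n = 3), and of mRpL41, a mitochondrial ribosomal protein gene, at -138 bp in 2R:15217562-15217946 with 2031 ± 341 (SD, n = 3). The peak nearest to CG4004 was the exception in distance, 5007 bp downstream of that gene's start site, in a non-coding exon of lncRNA:Vinr at X:12750834-12751685 (1699 ± 293, SD, n = 3).

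The remaining 4 of these 10 peaks were all promoter-proximal. Gapdh2, which encodes a glycolytic enzyme, had its summit at -166 bp in X:15867745-15868216 with a signal of 1731 ± 292 (SD, n = 3). CG11309 had a summit in its intron at 86 bp in 3L:21304317-21304801 with 1708 ± 551 (SD, n = 3). CG5611 had one at -105 bp in 3R:27635949-27636577 with 1620 ± 394 (SD, n = 3), and Art3, an arginine methyltransferase gene, one at -128 bp in 3R:15229324-15229747 with 1635 ± 281 (SD, n = 3). Of the 10 peaks, 7 had a summit within 200 bp of the nearest protein-coding start site. Each of the 10 ranked 20 or better in every replicate. TAATTA, the core word of many homeodomains, lay within 100 bp of the summit in 2 of the 10, at CG11050 and CG5611. These signals are the authors' values, and their spread includes any difference in scale between the replicate lists.

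Some gene bodies spanned many separate peaks. The gene with most IDR summits in its body or within 2 kb was kirre (FBgn0028369, X:2740384-3134532), which encodes an immunoglobulin protein of muscle founder cells, with 32 summits over 394149 bp. It had none within 1 kb of a start site. The strongest 5000 peaks of a replicate placed 18.3 ± 1.15 summits there (SD, n = 3). ush (2L:476220-540560), a cofactor of GATA factors, and sbb (2R:18278198-18357296) had 20 IDR summits each, with 15 ± 2 and 17 ± 1 in the replicates (SD, n = 3). Allowing for length, ush held 2.93 summits per 10 kb, shn (2R:11159086-11217394), a zinc finger gene of Dpp signalling, 2.89, and kirre 0.804. The other 6 of the 10 genes were CG1677 (19 summits), the kinase gene Tlk (17), and sick, the ecdysone-induced receptor gene Eip75B and CG32264 (16 each), and the basic leucine zipper gene Pdp1 (15). These counts include peaks at other genes inside or beside the body: the strongest peak counted for ush is the one nearest to cbt, the strongest for CG1677 (X:7281089-7405797) is at the start of CBP (X:7337352-7342731), and w lies inside kirre.

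Promoter-proximal sequence held more IDR peaks than random placement gave. A summit lay within 500 bp of an annotated transcription start site in 3146 of 7092 IDR peaks, or 44.4% (95% exact binomial interval 43.2 to 45.5%, counting error over peaks only), against 13.6% of randomly placed peaks, a 3.26-fold excess. In the strongest 5000 peaks of each replicate the share was 46.0% ± 0.828 (SD, n = 3). Exons away from promoters held 2.62% of IDR peaks against 19.7% at random, and intergenic sequence 13.6% against 27.3%. Each of these 3 shares lay outside all 1000 random placements (two-sided permutation p = 0.001, the smallest that 1000 placements can give). Introns held 39.4% of IDR peaks and 39.4% of random placements (permutation p = 0.977), but this depended on the promoter limit: with 200 bp introns held 45.6% against 41.5% at random, more than the promoters at 31.3%, and with 1000 bp 32.2% against 36.1% (permutation p = 0.001 for each). The strongest 1000 IDR peaks had 30.6% in introns (permutation p = 0.001).

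**Figure D1:**
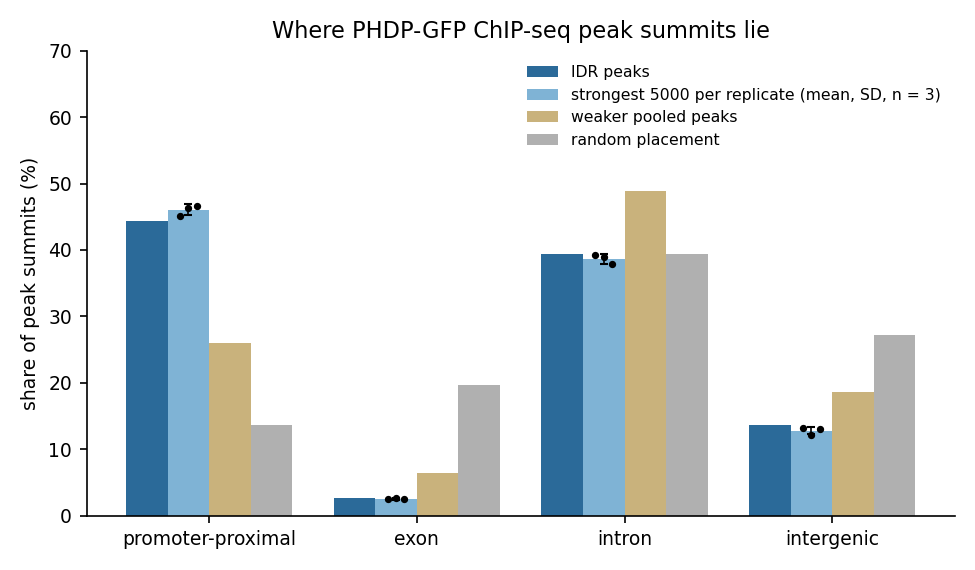
Share of peak summits (%) in promoter-proximal sequence (within 500 bp of a start site), exons, introns and intergenic sequence, for the IDR peaks, the strongest 5000 peaks of each replicate (bar, mean; error bar, SD, n = 3; points, replicates), the weaker peaks of the pooled list and random placement (mean of 1000). The promoter-proximal share is 44.4% in the IDR peaks, 26.0% in the weaker pooled peaks and 13.6% at random.

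The promoter-proximal share went with peak strength. Within each replicate, the strongest 5000 peaks were promoter-proximal more often than those ranked below 7092, by 18.7 percentage points ± 0.871 (SD, n = 3), and in the same direction in all 3 replicates. The share was 49.5% ± 0.782 among ranks 1 to 2500 and 18.9% ± 0.887 among ranks 27501 to 30000 (SD, n = 3). The replicate lists reach down to −log10 q values of 0.358, 0.429 and 0.388, so they include peaks of weak support. How far false calls lower the share among weak peaks was not tested. Among the IDR peaks themselves the difference in signal was small: the median signal of promoter-proximal peaks exceeded that of other peaks by 0.14 ± 0.02 on the log2 scale (SD, n = 3). It was above 0 in all 3 replicates, for which the smallest two-sided exact sign-flip p is 0.25. With a promoter limit of 200 bp the difference was 0.01, and without replicate 2 or 3 it was 0.24. In the IDR peaks at or above the median signal, with all replicates kept, it was 0.20.

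The peaks were spread over all chromosome arms. Arm 3R held 23.0% of IDR peaks and 24.0% of the placeable bases, 3L 22.0% and 20.9%, 2L 19.1% and 17.6%, 2R 17.9% and 18.9%, and X 17.6% and 17.6%. Chromosome 4, the small and largely heterochromatic chromosome, held 31 IDR peaks, or 0.437% (95% exact binomial interval 0.297 to 0.620%), against 0.996% of bases. In the replicates its share was 0.387% ± 0.0924 (SD, n = 3). Without replicate 2, in a stricter set of 4999 IDR peaks, it was 0.260%, below that interval. The strongest 1000 IDR peaks, with all replicates kept, gave 0.30%.

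Sequences at the summits were searched for 18 words fixed in advance, each compared with a window centred 500 bp away by a two-sided exact McNemar test with Benjamini-Hochberg adjustment over the 18 words. TAATTA was present within 100 bp of the summit in 18.8% of IDR peaks and in 11.6% of flanking windows (exact adjusted p = 3.4e-31). The palindrome TAATNNNATTA (P3), bound by pairs of paired-like homeodomains, was present in 3.07% against 1.38% (exact adjusted p = 1.7e-11), and TAATNNATTA (P2) in 2.65% against 1.06% (exact adjusted p = 3.1e-12). In the strongest 5000 peaks per replicate the excess was 8.21 ± 0.735 percentage points for TAATTA, 1.99 ± 0.0987 for P3 and 1.77 ± 0.153 for P2 (SD, n = 3). Summit windows were poorer in GC than flanks, 34.6% against 43.0% in the IDR peaks. Against the same summit windows shuffled with their dinucleotides kept, TAATTA was less frequent than in the shuffled sequence (18.8% against 21.2%, exact adjusted p = 0.00054), P2 did not differ detectably (2.65% against 2.75%, exact adjusted p = 0.75), and P3 remained more frequent (3.07% against 2.37%, exact adjusted p = 0.016).

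Words of housekeeping promoters stood out in fold. The DNA replication-related element TATCGATA (DRE) was present in 3.12% of IDR peaks against 0.451% of flanks, 6.91-fold (exact adjusted p = 2.2e-35), and GGTCACAC (Motif 1, bound by M1BP) in 2.19% against 0.578%, 3.78-fold (exact adjusted p = 8.6e-17). Both excesses were seen in promoter-proximal peaks, a split chosen after the data were seen: 6.48% against 0.636% for DRE and 4.48% against 0.890% for Motif 1. Presence at the summit differed between promoter-proximal and other peaks for both (two-sided Fisher's exact test, adjusted p = 7.4e-53 and 4.8e-35). In the other peaks DRE was present in 0.431% against 0.304% (exact adjusted p = 0.55) and Motif 1 in 0.355% against 0.329% (exact adjusted p = 1). The forkhead word TGTTTAC was present in 7.61% against 4.62% (exact adjusted p = 4.1e-13), and the GATA word AGATAA in 16.7% against 10.8% (exact adjusted p = 3.8e-24), but GATA did not differ detectably from shuffled windows (17.2%, exact adjusted p = 0.52). Of the 18 words, 8 were more frequent at summits and 5 were less frequent, among them the CA repeat (3.41% against 6.80%), the E-box CAGCTG (8.02% against 9.76%) and the GAGA word (3.55% against 4.62%). These 3 turned direction against shuffled summit windows, where they exceeded them by 2.44, 5.63 and 2.85 percentage points (exact adjusted p = 7.4e-25, 3.3e-53 and 1.3e-37). The shuffled windows held them in only 0.973%, 2.40% and 0.705%, far below the flanks as well. That excess therefore does not show enrichment at summits. Flank windows, which were richer in GC, were not shuffled, so whether it is particular to summits stays open. The E-box CACGTG was also less frequent at summits than in flanks (1.66% against 2.81%, exact adjusted p = 1.1e-05). It was less frequent than in shuffled windows too (2.31%, exact adjusted p = 0.011). Against flanks it did not pass in promoter-proximal peaks (2.03% against 2.64%, exact adjusted p = 0.17) or in the strongest 1000 (exact adjusted p = 0.088). Against flanks, in the split by promoter, GAGA was more frequent at summits of promoter-proximal peaks (4.83% against 3.62%, exact adjusted p = 0.032) and less frequent in the other peaks (2.53% against 5.42%, exact adjusted p = 3.8e-10). CAGCTG did not differ detectably in promoter-proximal peaks (10.4% against 10.0%, exact adjusted p = 0.79) and was less frequent in the other peaks (6.16% against 9.53%, exact adjusted p = 7.7e-08). The calls of the AP-1 word TGANTCA (5.26% against 4.26%) and of the Runt word TGTGGTT (2.14% against 2.78%) were lost when any replicate was left out. For AP-1 the difference fell from 1.00 to between 0.51 and 0.67 percentage points, while for Runt it stayed between -0.60 and -0.58 against -0.63 in the smaller sets. Without replicate 2 the Motif 1 excess fell from 1.61 to 0.960 percentage points, and the difference went from -1.73 to -2.62 for CAGCTG and from -1.07 to -1.92 for GAGA, which stood at -1.73 without replicate 3. These sets are also stricter. In the IDR peaks at or above the median signal, with no replicate left out, AP-1 stood at 0.17 and Runt at -0.39 percentage points, neither called. Motif 1 stood at 0.51, CAGCTG at -2.62 and GAGA at -2.40 there. The moves can therefore not be told apart from an effect of peak strength. Among the strongest 1000 IDR peaks the DRE excess no longer passed (1.20 percentage points, exact adjusted p = 0.086) and Motif 1 was at -0.10 percentage points.

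**Figure D2:**
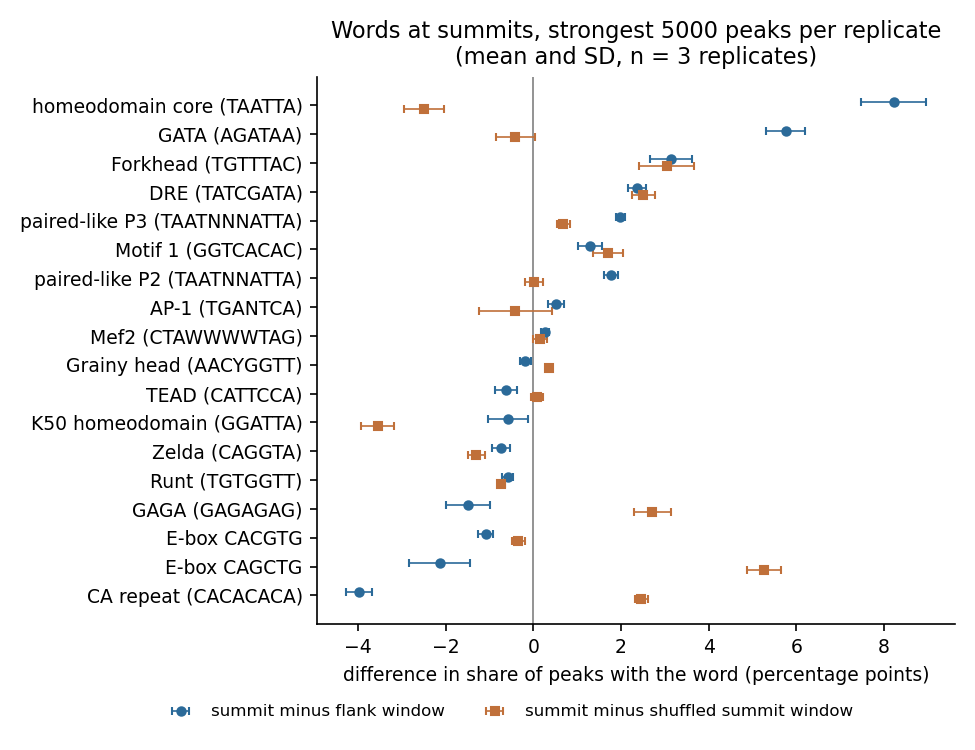
Difference in the share of peaks holding each of 18 words (percentage points) between the summit window and a window centred 500 bp away (circles) or the same summit window shuffled with its dinucleotides kept (squares), over the strongest 5000 peaks of each replicate (mean and SD, n = 3). TAATTA lies at 8.21 against flanks and at -2.49 against shuffled windows, while the forkhead word, DRE, P3 and Motif 1 lie above 0 in both.

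Gene lists fixed in advance showed ribosomal protein genes as the list most often bound. A gene was counted as bound when an IDR summit lay within 1 kb of one of its start sites, which held for 4031 of 13945 protein-coding genes (28.9%). Of the cytoplasmic ribosomal protein genes, 78 of 92 were bound, or 84.8% against 28.5% of other genes (two-sided Fisher's exact test, adjusted p = 1.0e-27 over 16 lists). The strongest 5000 peaks per replicate gave 80.8% ± 1.26 (SD, n = 3). In the IDR peaks, random lists of the same gene lengths gave 21.6% on average. The 3 bound members with the strongest peaks were RpS27 (summit at -4 bp, 3R:25247261-25247785, signal 480 ± 56.7, SD, n = 3), RpL7 (in its 5' UTR at 40 bp, 2L:10200869-10201228, signal 470 ± 63.6, SD, n = 3) and RpL34b (at -138 bp, 3R:9401175-9401575, signal 436 ± 30.8, SD, n = 3). RpS26 and RpL7-like were the longest members with no summit within 1 kb.

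Sensory receptor and histone genes were rarely or never bound. Of 119 odorant and gustatory receptor genes, 3 were bound, or 2.52% against 29.1% of other genes (Fisher's exact test, adjusted p = 4.2e-13). These were Or88a (summit at -612 bp, 3R:14108516-14109021), Gr32a (at -758 bp, 2L:11113137-11113441) and Or9a (at -999 bp, X:10460477-10460872), with signals of 248 ± 62.7, 180 ± 18.1 and 112 ± 13.4 (SD, n = 3). Gr28b and Gr39a were the longest members without one. The summits counted for Gr32a and Or9a were promoter-proximal, so each lay within 500 bp of a start site of another gene. None of the 111 replication-dependent histone genes was bound (Fisher's exact test, adjusted p = 4.8e-16), among them His1:CG31617 and His1:CG33801. Histone genes exist as near-identical tandem copies, where reads are hard to place, so the absence of peaks there is uncertain. The test also counts these copies as independent genes, so its p value overstates the evidence.

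The other 13 lists did not pass the adjusted test against all other genes. Against 10000 random lists of the same gene lengths, several nevertheless stood low: paired-like homeobox genes (12% against a mean of 39.9%, percentile 0.125), neuronal genes (16.7% against 43.9%, percentile 0.25), Hox genes (0% against 46.5%, percentile 0.355), heart and mesoderm regulators (7.14% against 36.9%, percentile 0.645), hemocyte genes (15% against 36.3%, percentile 1.98) and epidermal genes (22.2% against 42.3%, percentile 3.98). Notch pathway genes stood at percentile 96.2. These percentiles are not adjusted for the 16 lists. Against all other genes, the direction of some of these lists changed with how peaks were linked to genes. With the nearest start site at any distance, heart and mesoderm regulators stood at 50% against 28.7% of all other genes, neuronal genes at 33.3% against 28.8% and epidermal genes at 38.9% against 28.7%. With a summit in the gene body or within 2 kb, neuronal genes stood at 50% and epidermal genes at 55.6% against 42.4%, but heart and mesoderm regulators at 35.7%. Paired-like homeobox genes stayed below other genes under both rules, at 24% against 28.8% and 28% against 42.4%. Hemocyte genes did too, at 20% and 30% against the same shares. These comparisons are not matched on gene length, so they do not test the standing against random lists. None of them passed (exact adjusted p from 0.21 to 0.83). Of 15 Notch pathway genes, 8 were bound (53.3%, exact adjusted p = 0.19), among them numb, neur, E(spl)m3-HLH and E(spl)m7-HLH. That list passed in the strongest 1000 IDR peaks (26.7% against 6.29%, exact adjusted p = 0.049), in the IDR peaks at or above the median signal (46.7% against 17.2%, exact adjusted p = 0.032) and without replicate 2 (53.3% against 21.5%, exact adjusted p = 0.027). It did not pass without replicate 1 or 3 (exact adjusted p = 0.18 and 0.12), with the nearest start site (0.12) or with the gene body (0.52). These p values are not adjusted over the settings. Of 12 glial genes, 6 were bound (50%, exact adjusted p = 0.24), including moody and Gs2. Of 25 paired-like homeobox genes, the class of PHDP itself, 3 were bound: PHDP, eyg and CG11294 (12%, exact adjusted p = 0.22). Of 24 neuronal genes, 4 were bound: elav, scrt, Syx1A and fne (16.7%, exact adjusted p = 0.42). None of the 8 Hox genes had a summit within 1 kb of a start site (exact adjusted p = 0.24), although counting the gene with the nearest start site at any distance gave 75.0% against 28.7% (exact adjusted p = 0.036). That comparison is matched neither on gene length nor on spacing between genes. With the gene body rule Hox genes stood at 50% against 42.4% (exact adjusted p = 0.78). Muscle genes (8 of 25), heat shock genes (7 of 19), gut and fat body genes (6 of 16), segmentation genes (5 of 22), tracheal genes (4 of 17), epidermal genes (4 of 18), hemocyte genes (3 of 20) and heart and mesoderm regulators (1 of 14, tin) had exact adjusted p values from 0.22 to 0.83. Leaving out 1 replicate, which lowered the share among genes outside each list to about 22%, moved some of these lists further. Segmentation genes went from 22.7% to 4.55% without replicate 1 and 9.09% without replicate 2 or 3. Gut and fat body genes went from 37.5% to 18.8% and muscle genes from 32% to 20% without replicate 1 or 3, and tracheal genes from 23.5% to 11.8% without replicate 3. Leaving out a replicate also gave a smaller, stricter peak set. The IDR peaks at or above the median signal, with no replicate left out, gave 4.55% for segmentation and 18.8% for gut and fat body genes. They gave 24% for muscle and 17.6% for tracheal genes, against 17.2% of other genes in each case. For segmentation and gut and fat body genes, the moves can therefore not be told apart from an effect of peak strength. Muscle and tracheal genes fell further without a replicate than in that set, and muscle genes stayed at 32% without replicate 2. With 25 and 17 genes in these lists, few genes move the shares, so no conclusion is drawn. Members of lists outside the 3 that passed were named after their values were seen.

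**Figure D3:**
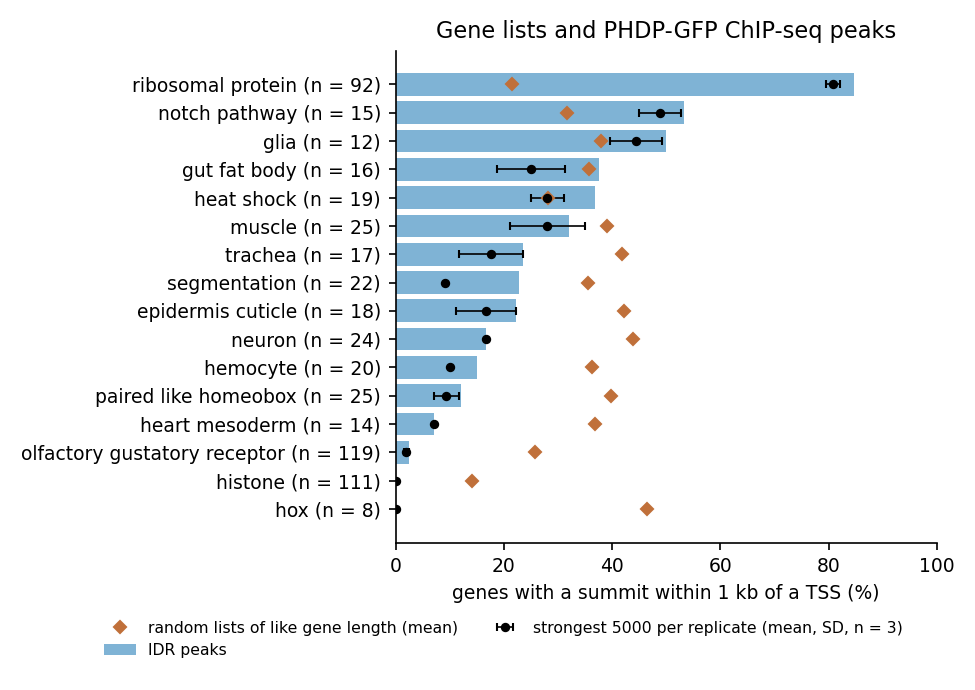
Share of each list's genes (%) with a summit within 1 kb of a start site, for the IDR peaks (bars), the strongest 5000 peaks per replicate (points, mean and SD, n = 3) and random lists of the same gene lengths (diamonds, mean). The random lists use the IDR peaks, so they compare with the bars and not with the points. Ribosomal protein genes stand at 84.8% and odorant and gustatory receptor genes at 2.52%.

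The region around PHDP itself carried peaks at a density within the range of other genes. PHDP (FBgn0025334, 2R:23883136-23884440, minus strand) had an IDR peak at 2R:23884824-23885140, with its summit in intergenic sequence at -535 bp from its start site and a signal of 360 ± 44.3 (SD, n = 3). Within 50 kb of the gene lay 33, 43 and 41 peaks in replicates 1, 2 and 3, at a mean percentile of 72.1 ± 8.25 (SD, n = 3) among 1000 random protein-coding genes. The IDR list had 13 peaks there, at percentile 87.2. Of these, 11 lay at lower coordinates than the gene and 2 at higher coordinates, namely the peak upstream of PHDP itself and one in SERCA. The strongest was at 2R:23850196-23850581, 108 bp upstream of the start site of eIF6, a ribosome assembly factor gene. The gene w, a common marker of transgenic flies, had no IDR summit within 1 kb of a start site, and its surroundings (X:2790599-2796466 with 50 kb either side) stood at percentile 45.9 ± 2.73 (SD, n = 3). With 100 kb either side they stood at percentile 29.7 ± 2.27 (SD, n = 3).

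**Figure D4:**
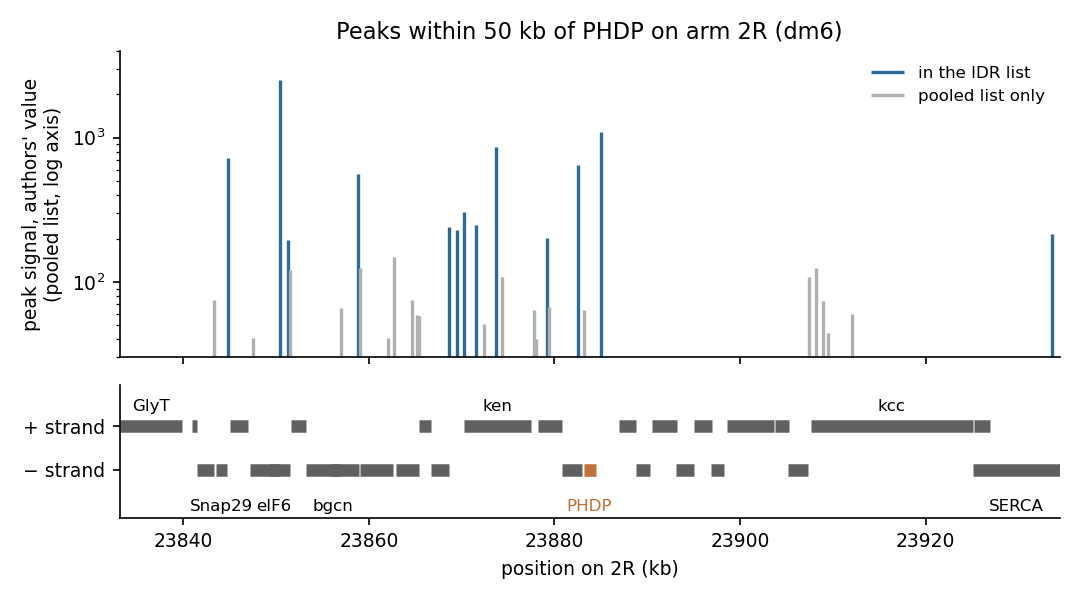
Peaks of the pooled list within 50 kb of PHDP on 2R (dm6), by position (kb) and the authors' signal (log axis), with protein-coding genes below by strand. Of the 13 IDR peaks, 11 lie at lower coordinates than PHDP and 2 at higher coordinates, the peak upstream of PHDP and one in SERCA.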

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

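The tests of extra copies around PHDP and of repeated sequence behind CACTGAGA were chosen after the result was seen, and the other tests of explanations were set before their result was seen.

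Replicate 3 listed 5 mitochondrial peaks, and the other replicates listed 0. They lie outside the chromosome arms analysed and were noted because they are a signal in data the comparisons do not use. The strongest ranked 6 in that replicate's list.

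TAATTA was more frequent at summits than in flanks. One technical explanation is the AT-rich composition of summits, which predicts no excess over shuffled summit windows. The summit share lay at -2.38 percentage points relative to them (SD 0.446, n = 3 replicates), so composition alone may account for the excess over flanks. The test cannot decide this, because flanks were not shuffled too. K50, for instance, was present in 9.90% of shuffled windows, against 5.77% of summits and 6.13% of flanks. A general deficit of genomic against shuffled sequence is thus not excluded for TAATTA. Placement without regard to the summit is argued against by the median distance of matches, 42.5 bp from the summit against 49 bp for uniform placement (SD 0.577, n = 3). That closeness may itself follow composition, which also changes towards the summit, and this stays open. For the P3 palindrome the excess over shuffled windows was 0.705 percentage points (SD 0.155, n = 3). Flank windows were not shuffled, so a general excess of genomic over shuffled sequence is not excluded. Tested apart, neither promoter-proximal peaks (3.18% against 2.45% shuffled) nor other peaks (2.99% against 2.31%) passed. Whether composition is the whole cause for P3 therefore stays open. P3 matches lay a median of 48 bp from the summit, as far as the 48 bp of uniform placement (39.5 ± 5.89 bp in the replicates, SD, n = 3). No biological explanation was tested, since the series has 1 group.

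Of the 13 IDR peaks within 50 kb of PHDP, 11 lay at lower coordinates than the gene and 2 at higher coordinates. Extra copies of the locus in the transgenic line might raise peaks over the whole interval. The number of peaks below the strongest 7092 there stood at percentiles 46.1, 66.6 and 61.9 among random genes in replicates 1, 2 and 3, and the IDR peaks at 87.2. Copies could also lift peaks into the strong set, and no value here measures what they would give, so this stays open. No biological explanation was tested.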

How the results depend on the processing

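The motif tests split by promoter-proximal and other peaks, the arm shares without each replicate and the paired-like list without PHDP were chosen after the result was seen. Promoter-proximal and intergenic shares stayed above and below random, respectively, in all alternatives run, as did the TAATTA and P3 excess over flanks. Sequencing depth is unknown, so its effect on these values was not examined. Of 418 alternative values, 315 were unchanged in direction and call, or within the replicate spread or 1.5-fold, and 36 turned direction, 24 of them where neither value passed its test. The cause of the changes below was not tested.

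Replicate overlap was 80.2% with any 1 bp overlap, 63.7% with 50% reciprocal overlap, 83.4% for the strongest 1000 and 68.9% for the strongest 10000 peaks, and 75.7 to 77.5% leaving out 1 replicate. The signal correlation between replicates was 0.843 with summits within 50 bp and 0.779 to 0.812 leaving out 1 replicate. The intron share was 45.6% with a 200 bp promoter limit, above random, 32.2% with 1000 bp, 30.6% in the strongest 1000 peaks, and 39.2 to 40.5% leaving out 1 replicate. Arm shares in those 1000 peaks were 20.1% (2L), 17.2% (2R), 22.2% (3R), 0.30% (4) and 18.4% (X); leaving out 1 replicate gave 17.6 to 17.7% for 2R, 23.0 to 23.3% for 3R and 0.260 to 0.373% for 4. The promoter signal difference (log2) was 0.20 in IDR peaks at or above the median, 0.21 in the strongest 1000, 0.012 with 200 bp, and 0.13 to 0.24 leaving out 1 replicate.

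The strongest 1000 peaks called 5 words higher and 3 lower, the window 500 bp to the other side called 8 lower, and promoter-proximal peaks 3 lower. Some words not called in the main test gained a call. Against the window on the other side these were K50 (-1.20 percentage points), Zelda (-0.96) and TEAD (-0.87), lower, and Mef2 (0.45), higher. In promoter-proximal peaks Zelda was called lower (-1.94), and against shuffled windows K50 (-4.13) and Zelda (-1.69) were. With windows of 50 bp Zelda (-0.62) and TEAD (-0.52) were called lower and Mef2 (0.32) higher. Against shuffled windows the difference (percentage points) turned to -2.38 for TAATTA, -0.10 for P2, -0.32 for AP-1, -0.49 for GATA, 2.85 for GAGA, 5.63 for CAGCTG and 2.44 for the CA repeat. In promoter-proximal peaks it turned to 1.21 for GAGA, called higher, and 0.32 for CAGCTG, not called, and in the strongest 1000 to -0.10 for Motif 1. Words that passed in neither setting turned to 0.25 for Grainy head and 0.17 for TEAD against shuffled windows, 0.028 for Grainy head against the window on the other side, 0.064 for it in promoter-proximal peaks, 0.63 for Zelda and 0.18 for K50 in the other peaks, and 1 for K50 and -0.50 for Mef2 in the strongest 1000. Lists higher numbered 2 in IDR peaks at or above the median and in the strongest 1000, where Notch was added, and with the nearest start site at any distance, where Hox genes stood at 75.0%; leaving out 1 replicate gave 1 to 2. Lists that passed in neither setting also turned direction relative to other genes: with the nearest start site, heart and mesoderm 50%, trachea 47.1%, epidermis 38.9%, segmentation 36.4% and neurons 33.3%; with the gene body, epidermis 55.6%, and Hox and neurons 50%. Trachea did so in the peaks at or above the median (17.6%) and heart and mesoderm in the strongest 1000 (7.14%). Leaving out 1 replicate gave 20 to 32% for muscle and 18.8 to 25% for gut and fat body, below other genes without replicate 1 or 3. The PHDP percentile was 81.4 with 20 kb and the w percentile 29.7 with 100 kb.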

Other observations

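All gene lists and the 8-base word search in this part were chosen after the data were seen; the test of the word in weaker peaks was set before its result was seen, and the test of repeated sequence after.

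Further housekeeping and chromatin genes were among those bound. Of 73 mitochondrial ribosomal protein genes, 36 had an IDR summit within 1 kb of a start site (49.3% against 28.8% of other genes, Fisher's exact test, adjusted p = 0.0006 over 5 lists). In the strongest 5000 peaks per replicate the share was 37.4% ± 1.58 (SD, n = 3). In the IDR peaks, random lists of the same gene lengths gave a mean of 18.2%. Its strongest peaks were at mRpL41, mRpS10 (summit at -129 bp, 3R:15229324-15229747, the peak also counted for the neighbouring Art3) and mRpS23 (at -384 bp, 2L:13835255-13835691), with signals of 2031 ± 341, 1635 ± 281 and 1402 ± 326 (SD, n = 3). Of 20 Polycomb and trithorax group genes, which keep developmental genes repressed or active, 11 were bound (55.0% against 28.9%, Fisher's exact test, adjusted p = 0.028), led by ph-p (X:2137176-2137577, 1303 ± 308), brm (3L:15982820-15983193, 708 ± 128) and E(z) (3L:10637810-10638214, 572 ± 123; SD, n = 3 for each). For the Polycomb and trithorax list the strongest 5000 peaks per replicate gave 36.7% ± 2.89 (SD, n = 3). In those smaller sets 22.7% of all protein-coding genes were bound on average. In the IDR peaks, random lists of the same gene lengths gave 39.1%, with the list at percentile 92.3, so it did not stand apart from genes of like length. Both lists were drawn up because members stood among the strongest peaks, so their counts are not independent evidence.

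Cuticle protein and digestive protease genes were seldom bound. Of 70 cuticle protein genes, 4 were bound (5.71% against 29.0%, Fisher's exact test, adjusted p = 9.5e-06), with Cpr73D the strongest (3L:16956785-16957070, signal 231 ± 73.9, SD, n = 3). Of 27 digestive protease genes, 1 was bound, etaTry (3.70% against 29.0%, exact adjusted p = 0.0036). Of 48 proteasome genes, 13 were bound (27.1% against 28.9%, exact adjusted p = 0.87), so the list did not differ detectably from other genes.

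The 8-base word with the highest standardized excess at IDR summits was CACTGAGA, present in 246 of 7092 peaks (3.47%) against 0.423% of flanks. It was present in 4.84% of peaks away from promoters (flank 0.380%) and 1.75% of promoter-proximal peaks (flank 0.477%), a difference in the direction opposite to DRE (Fisher's exact test, adjusted p = 3.0e-13 over 3 words). Its matches lay a median of 69.5 bp from the summit, farther than the 48.5 bp of uniform placement (67.2 ± 3.21 bp, SD, n = 3). Being picked by chance among all 8-base words is argued against by the weaker pooled peaks, not used to pick it. There the summit share exceeded the flank by 0.877 percentage points (exact McNemar p = 1.9e-22). Peaks ranked below 7092 in each replicate gave 0.923 ± 0.107 (SD, n = 3), but they can include sites of IDR peaks. Copies of 1 repeated sequence are argued against by 0% of these peaks sharing at least 35 of 40 flanking bases with another. No biological explanation was tested.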
